A study of Nicotiana attenuata with 24 samples.

How the data were processed

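Each of the 24 samples was hybridised to a custom Agilent array with 62976 spots, of which 61657 were not control spots. Per the labels, each replicate was a biological replicate pooled from leaves of 2 samples, and Cy3-labelled cRNA was made from the RNA. Per the file headers, the scans were read with Agilent Feature Extraction 10.7.3.1, while the submitters' processing notes name Agilent Feature Extraction 9.5. The deposited scanner files give the processed signal, the median signal and the local background of every spot as intensity on a linear scale, per the file headers, already background-corrected for the processed signal and not scaled between arrays. A table of log2 values deposited by the authors holds 57157 probes for the same arrays. Its scaling is not given in the sources used here. Its columns have medians between 5.85 and 5.87, 75th percentiles between 8.53 and 8.55 and one shared maximum of 18.67, a pattern that quantile normalization between arrays leaves, and results from it carry that scaling. Each column correlates across probes with the log2 median signal of its array with r between 0.992 and 1.00, so the direction is that of the signal, and no further centring could be established.

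Spots with an outlier flag were left out (129 to 244 per array), no spot was saturated and none of the processed signals was at or below 0. Spots of one probe were averaged on the log2 scale, and 500 of the 57157 probes had 10 spots. Over the 145 of these detected on all arrays, the median SD within an array was 0.07 on the log2 scale. The log2 processed signal minus the 75th percentile of its array was the level used throughout. A probe was tested when well above background on all 3 arrays of at least 1 group, which kept 33528 probes and left out 23629. Group differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, with a column for each of the 8 groups over all 24 arrays), with Benjamini-Hochberg adjustment over the tested probes for each comparison and a threshold of 0.05. Where a group had no array well above background for a probe, the fold is a bound: the mean of the brighter group against the mean, per array, of the higher of the lowest signal among probes well above background and the signal of the probe itself. Where only some arrays of the dimmer group were well above background, the fitted value is given with the same bound, in which the remaining arrays are treated in that way. Each bound is on the difference of group means: it allows for the background and not for the spread between arrays, so single arrays can differ by less. The expected overlap of independent lists is the product of both counts over the probes tested. The spread of each probe comes from all 24 arrays and enters every comparison, so lists are not independent even where their group means share no array. Tables and figures were made with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

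The fit was tested on simulated data for the comparison of the lines at 5 h after OS, with 33507 probes given their own mean and spread. Of 100 probes changed by 1 on the log2 scale 54 were called, and of 100 changed by 2, 92 were called, with 6 calls among unchanged probes.

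The 3 slides, read from the arrays, were scanned once each. Slide 1 held 1 array of each group, and the other 16 arrays lay unevenly on slides 2 and 3, so each comparison is given with slide as a block and within the slides that hold all its groups. Probes were called on these same arrays, so their direction within a slide is no independent check, and the block is the test against the slides.

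Probes are named by model or locus identifiers, and 0 of them matched the gene table of 39977 RefSeq genes of the assembly NIATTr2 used here, so no gene names are given, and the silencing of MYB8 was not checked here on its own probe. For that reason the tests of 26 gene lists and of marker lists for other cell types, fixed before the data were examined, were not run. The probes named in the text were chosen by a rule fixed before the data were examined: per comparison, 1 probe per locus (the brightest on average), called, with no overlap between the arrays of the groups compared (for an interaction or an average, called only) and well above background on every array of at least 1 group, the 2 with the highest and the 2 with the lowest log2 fold change. Chance separates 3 against 3 arrays without overlap in 10% of cases. A locus can have several probes: of the 5998 loci with at least 2 tested probes, 4331 had a call in WT at 1 h after OS, 1048 with all probes higher and 1724 with all lower, and 79 loci had probes called in opposite directions. Among the named probes, 5 pairs had deviations from the group means correlated above 0.8: the 3 pairs given with their values, and PRID1968076876 with NIATv7_g01849.t1.cds1 (r = 0.826) and with NIATv7_g23271.t1.cds1 (r = 0.819). Probe sequences were not compared.

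Alternatives covered the background correction (normexp with an offset of 50), the scaling, the authors' table, the filter on dim probes, replicate number and slide as blocks, the arrays in the fit, the variance model, array weights, a minimum log2 change of 1 and leaving out each array in turn with the tested probes kept. Normexp was run on the median signals, since the mean signals that had been planned were not used here.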

Results

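Leaf transcripts of *Nicotiana attenuata*, a wild tobacco, were measured in 24 samples, each on its own single-colour (Cy3) microarray. Wild-type (WT) plants were compared with ir-MYB8 plants, in which an inverted-repeat construct silences MYB8, a MYB transcription factor known to control the synthesis of phenolamides, a class of herbivore defence metabolites. Leaves were either left untreated (control) or wounded with a pattern wheel and supplied with 20 µL of oral secretion (OS) of the tobacco hornworm *Manduca sexta* at a 5-fold dilution. Because the control was not wounded, every OS effect below is that of wounding and OS together. Leaves were harvested at 1 h or 5 h, which with 2 lines and 2 treatments made 8 groups of 3 arrays. Each array carried 57157 plant probes, and between 28011 and 36909 of them were well above background on an array. The number of arrays limits the precision of every value. Levels are log2 signals relative to the 75th percentile of their array, which lay between 241 and 544 signal units. Sizes of change differed with the processing: of 48 fitted values of the named probes, 46 were smaller by over 1.5 times with normexp on the median signals with an offset of 50, and 45 with the authors' deposited values. An added offset of 50 shrinks a fold against a dim signal by construction. How much each step accounts for, also with the authors' values, was not tested. In all, 33528 probes were tested, which stood for 21649 numbered gene models or loci and for probes with a PRID identifier. The array names its targets by model number alone, so the probe of the silenced gene is not named here, and genes are given by identifier.

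The largest source of variation was the treatment. The first principal component held 60.4% of the variance and set the OS groups at 1 h apart from the others, and the second held 18.3% and set the OS groups at 5 h apart. The third, with 5.36%, separated untreated leaves of 1 h from those of 5 h. Replicate arrays of a group correlated across probes with r between 0.975 and 0.991. The lowest r was in untreated ir-MYB8 leaves at 5 h, where the median SD of a probe was 0.270, against 0.168 to 0.220 in the other groups.

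**Figure D1:**
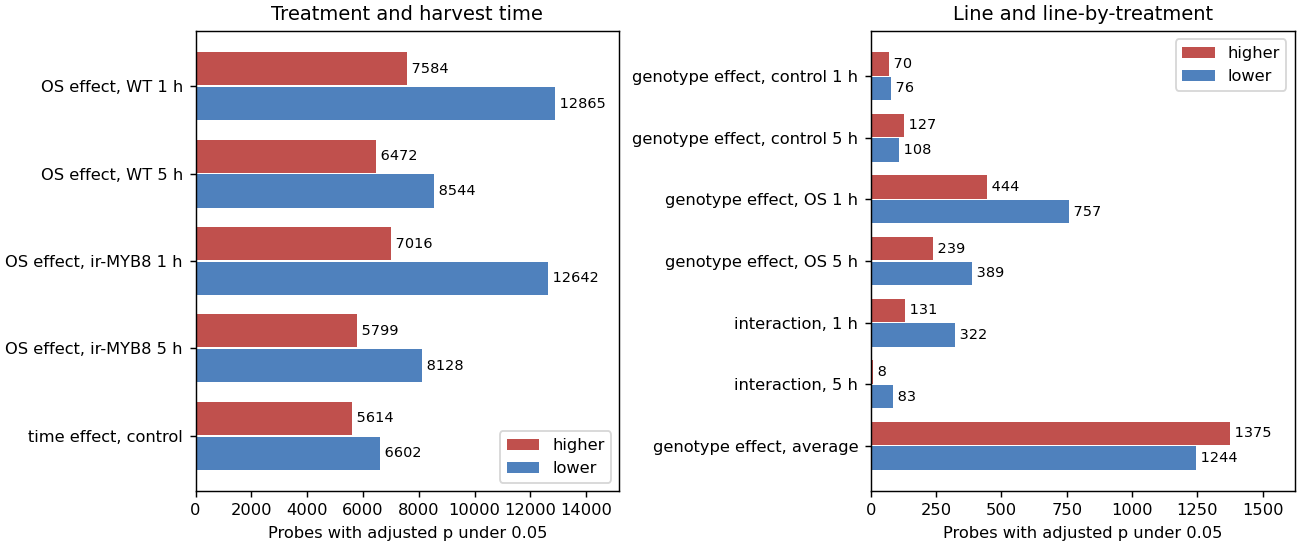
Number of probes called higher (red) or lower (blue) in each comparison, on a linear axis that starts at 0 and differs between the panels. OS effects called 13927 to 20449 probes, while comparisons between the lines within a condition called 146 to 1201.

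The first question was what OS changed in WT leaves at 1 h. The transcripts of 7584 probes rose and those of 12865 fell, together 61.0% of the probes tested. Among the called probes, 5439 rose and 6186 fell by at least 1 on the log2 scale, and 2090 rose and 589 fell by at least 3. The majority of falls thus did not hold among the largest changes. Among the highest rises was that of NIATv7_g47574.t1.cds1, which was not well above background in untreated WT leaves and reached 6.87 ± 0.18 (SD, n = 3) after OS, at least 2387-fold higher (limma adjusted p = 2.60e-14). NIATv7_g01849.t1.cds1 was likewise not well above background in the control and was at least 2331-fold higher after OS, at 6.84 ± 0.21 (SD, n = 3; limma adjusted p = 3.70e-12). Over the 24 arrays the deviations of these 2 probes from the group means correlated with r = 0.972, so they are not independent findings, and whether they read one transcript was not tested against probe sequences. NIATv7_g42750.t1.cds1 fell from 2.13 ± 0.21 to a level not well above background, at least 85.3-fold lower (n = 3; limma adjusted p = 1.18e-12). NIATv7_g10169.t1.cds1 went from 2.70 ± 0.02 to -4.25 ± 0.54 (SD, n = 3), a log2 fold change of -6.96 with an SE of 0.32 (limma adjusted p = 7.19e-13), and 1 of its 3 OS arrays was well above background, which makes it at least 108-fold lower. The median log2 fold change of all tested probes was -0.25 here, -0.10 in WT at 5 h, -0.27 in ir-MYB8 at 1 h and -0.12 in ir-MYB8 at 5 h. With normexp-corrected signals these medians were -0.14, -0.05, -0.15 and -0.18, and single changes stand against such shifts of all probes. With slide as a block 21008 probes were called, and within slides 1, 2 and 3 the called probes kept their direction in 99.6%, 99.7% and 99.4% of cases. Since probes were called on the same arrays, their direction within a slide is nearly fixed by the call, here and in the comparisons that follow, and is no test against the slides.

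In WT leaves at 5 h, the transcripts of 6472 probes were higher after OS and those of 8544 lower, 44.8% of the probes tested. NIATv7_g42176.t1.cds1 was at -4.92 ± 1.03 in untreated and 5.96 ± 0.23 in OS-treated leaves (SD, n = 3), a log2 fold change of 10.88 with an SE of 0.88 (limma adjusted p = 1.34e-08), but it was well above background on 1 of the 3 control arrays only, so the rise is at least 1414-fold. NIATv7_g23271.t1.cds1, which no control array measured above background, reached 3.62 ± 0.33 (SD, n = 3), at least 388-fold higher (limma adjusted p = 1.56e-09). NIATv7_g27700.t1.cds1 fell from -2.59 ± 0.08 (SD, n = 3) to a level not well above background, at least 4.59-fold lower (limma adjusted p = 1.81e-05). NIATv7_g10164.t1.cds1 fell by 4.16 on the log2 scale with an SE of 0.47 (n = 3; limma adjusted p = 1.06e-06), with 1 of its 3 OS arrays above background (at least 8.65-fold), and by 4.85 without WT OS 5 h replicate 1. Of the probes that rose at 1 h, 3414 were also higher at 5 h and 618 were lower, against 1464 and 1933 for independent lists. Of those that fell at 1 h, 5129 were still lower at 5 h and 1172 were higher, against 3278 and 2483. These arrays lay unevenly on the slides, and only slide 1 held both groups. There the called probes kept their direction in 99.9% of cases, and with slide as a block 14559 probes were called.

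In ir-MYB8 leaves, OS raised 7016 probes and lowered 12642 at 1 h. The probe NIATv7_g01849.t1.cds1 was again among the largest rises, from below background to 6.38 ± 0.25 (SD, n = 3), at least 1623-fold (limma adjusted p = 3.48e-11), and NIATv7_g00113.t1.cds1 rose at least 686-fold to 5.07 ± 0.24 (SD, n = 3; limma adjusted p = 1.68e-12). PRID1968078132 and NIATv7_g22124.t1.cds2 fell to levels not well above background, at least 27.8-fold and 24.3-fold lower (n = 3; limma adjusted p = 6.63e-11 and 2.16e-11). The deviations of this pair correlated with r = 0.917, so these are not independent findings either. At 5 h, 5799 probes were higher and 8128 lower after OS. PRID1968076876 and NIATv7_g42176.t1.cds1 rose, with log2 fold changes of 8.96 (SE 0.81) and 8.80 (SE 0.88; n = 3; limma adjusted p = 6.94e-08 and 2.60e-07). Their untreated arrays were far apart, at -4.98 ± 2.64 and -2.83 ± 2.60 (SD, n = 3), with 1 of 3 above background. The bounds on the mean rises were 184-fold and 439-fold (7.52 and 8.78 on the log2 scale). Within slide 2 the log2 rises were smaller than these bounds, at 6.155 and 5.853. The log2 fold changes were 10.42 and 10.25 without ir-MYB8 control 5 h replicate 2, and 7.85 and 7.74 without replicate 3. NIATv7_g42554.t1.cds1 and NIATv7_g27700.t1.cds1 fell to levels not well above background, at least 8.68-fold and 9.38-fold lower (n = 3; limma adjusted p = 3.41e-08 and 1.03e-05). The fitted log2 fold change of the last was -4.61, and -5.31 without ir-MYB8 OS 5 h replicate 2. The responses of the lines shared most of their calls at 1 h, with 6331 probes higher in both and 10421 lower in both, against 1587 and 4851 for independent lists. In opposite directions stood 47 probes at 1 h, as 43 rose in WT and fell in ir-MYB8 and 4 did the reverse. At 5 h, 4647 probes rose and 6173 fell in both lines, against 1119 and 2071 for independent lists. Across probes, which are not independent replicates, the log2 fold changes of the lines correlated with r = 0.948 at 1 h and r = 0.886 at 5 h, and these comparisons shared no array. Slide 1 alone held both ir-MYB8 groups at 1 h, where 99.2% of the calls kept their direction, and with slide as a block 18384 probes were called. At 5 h the slides gave 99.4%, 99.6% and 99.2%, and the block 14743 calls.

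**Figure D2:**
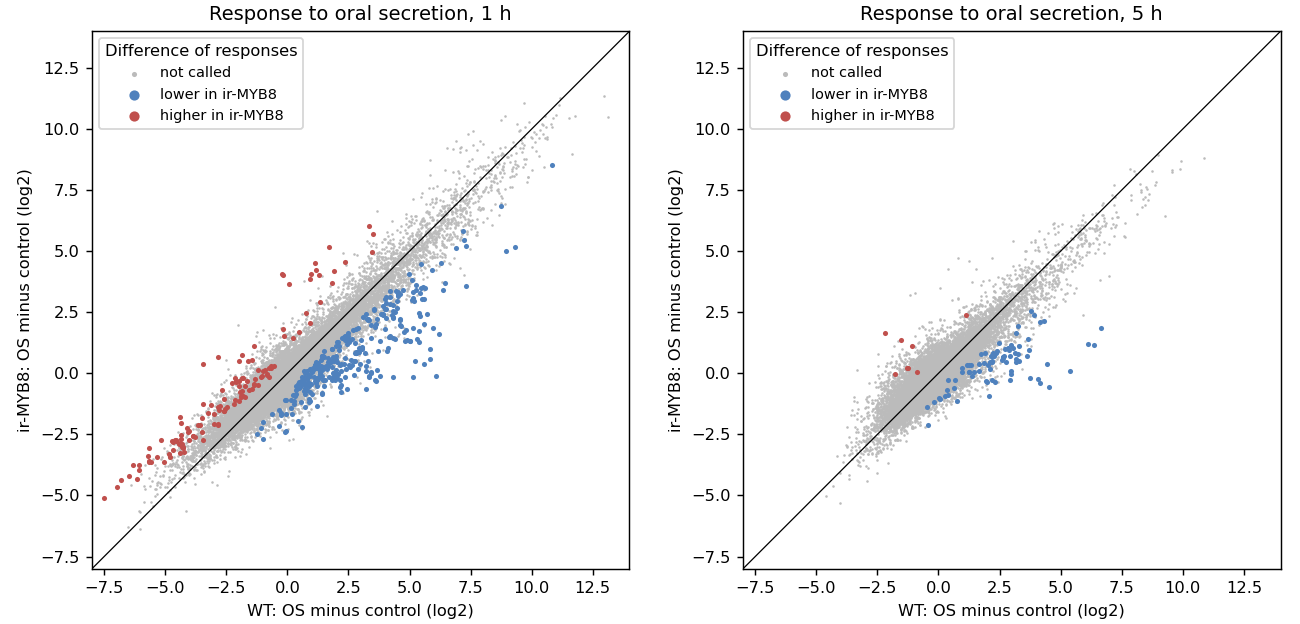
Log2 fold change of each tested probe after OS in WT (x axis) and in ir-MYB8 (y axis) at 1 h and 5 h, with equal values on the line. Probes whose responses differed between the lines are coloured. At 1 h 322 of them responded lower and 131 higher in ir-MYB8, and at 5 h 83 lower and 8 higher.

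Few probes were called between untreated leaves of the lines, which does not show that few differed: by limma 3822 of the 33528 tested probes at the 1 h harvest and 5642 at the 5 h harvest had an unadjusted p under 0.05. By chance alone a share of 0.05 of the tested probes falls there on average, and more or fewer where probes are correlated. They are therefore not counts of probes that differed. In ir-MYB8 leaves at the 1 h harvest 70 probes were higher and 76 lower than in WT, and counted by numbered gene model or locus 62 were higher and 50 lower. XLOC_014307.t1.cds1 was at -0.42 ± 0.05 (SD, n = 3) in ir-MYB8 and not well above background on any WT array, at least 15.2-fold higher (limma adjusted p = 1.28e-05). Its fitted log2 difference of 5.02 was 5.74 without WT replicate 1 and 4.40 without WT replicate 3. NIATv7_g38973.t1.cds1 was at least 6.61-fold higher (n = 3; limma adjusted p = 0.0198), but no longer called without any 1 of the 6 arrays other than ir-MYB8 replicate 2, with adjusted p from 0.0518 to 0.129, nor with normexp-corrected signals, where it was 0.173 (0.00827 to 0.173 over the alternatives). Its fitted log2 difference of 4.70 was 5.54 without ir-MYB8 replicate 2 and 3.82 without ir-MYB8 replicate 3. Lower in ir-MYB8 were NIATv7_g01522.t1.cds1, at least 3.08-fold (n = 3; limma adjusted p = 0.00308), and NIATv7_g39881.t1.cds1, at -3.75 ± 1.02 against -0.10 ± 0.83 in WT (SD, n = 3; limma adjusted p = 0.000139), with 2 of its 3 ir-MYB8 arrays above background (at least 11.7-fold). On slide 1 the difference of the last probe was -1.59 and on slide 2 -4.90. Every called probe kept its direction within slides 1 and 2, slide 3 held no ir-MYB8 array of this harvest, and with slide as a block 127 probes were called. The count fell to 89 without ir-MYB8 control 1 h replicate 3, to 85 without WT control 1 h replicate 3 and to 25 when only the 6 arrays compared were fitted. The small majority of lower probes turned without ir-MYB8 control 1 h replicate 2 (62 higher, 58 lower) and without WT control 1 h replicate 1 (57 higher, 46 lower), and without WT control 1 h replicate 2 it was gone (50 each).

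At the 5 h harvest, 127 probes were higher and 108 lower in untreated ir-MYB8 leaves. NIATv7_g24417.t1.cds3 was at -1.63 ± 0.63 (SD, n = 3) and not well above background in WT, at least 10.2-fold higher (limma adjusted p = 0.000432). XLOC_014307.t1.cds1 was at least 20.2-fold higher (n = 3; limma adjusted p = 4.53e-05). NIATv7_g43706.t1.cds1 was at -5.31 ± 0.59 in ir-MYB8 and 0.95 ± 0.43 in WT (SD, n = 3), a log2 fold change of -6.26 with an SE of 0.48 (limma adjusted p = 2.72e-07). NIATv7_g39881.t1.cds1 was lower by a log2 fold change of -5.60 with an SE of 0.45 (n = 3; limma adjusted p = 4.54e-07). Each of these 2 probes was above background on 1 of the 3 ir-MYB8 arrays, so they were at least 37.3-fold and 34.9-fold lower. Of the probes called at 1 h, 30 were also higher and 34 also lower at 5 h, against 0.265 and 0.245 for independent lists, and none was called in the opposite direction. The called probes kept their direction in 100% of cases within slides 1 and 3, slide 2 held no WT array of this harvest, and the slide block gave 234 calls. Without ir-MYB8 control 5 h replicate 1 the count was 114, without WT control 5 h replicate 3 it was 83, and with only the arrays compared 28. The majority of higher probes turned with a minimum log2 change of 1 (67 higher, 80 lower), with only the arrays compared (10 and 18) and without ir-MYB8 control 5 h replicate 1 (56 and 58) or 2 (143 and 153).

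At 1 h after OS 444 probes were higher and 757 lower in ir-MYB8. NIATv7_g39881.t1.cds1 stood at 4.78 ± 0.17 in WT and -1.96 ± 0.78 in ir-MYB8 (SD, n = 3), a log2 fold change of -6.74 with an SE of 0.45 (limma adjusted p = 6.71e-09). NIATv7_g43706.t1.cds1 was at 4.75 ± 0.18 in WT and -1.96 ± 0.69 in ir-MYB8 (SD, n = 3; limma adjusted p = 1.92e-08). Across the 24 arrays the deviations of these 2 probes correlated with r = 0.943, so here and in the other comparisons they are not independent findings. XLOC_014307.t1.cds1 was at least 15.3-fold higher in ir-MYB8 (n = 3; limma adjusted p = 2.34e-06). NIATv7_g23932.t1.cds1 was measured above background in ir-MYB8 and not in WT, at -1.65 ± 0.46 (SD, n = 3), at least 6.20-fold higher (limma adjusted p = 2.19e-05). On the normexp-corrected signals the split was 239 higher and 758 lower, while with array weights it turned, to 1926 higher and 1722 lower. The weights of WT OS 1 h replicates 1, 2 and 3 were 4.1, 0.438 and 0.610, so the weighted WT level rests mostly on replicate 1. The calls kept their direction in 99.9% of cases on slide 1 and 100% on slide 3, slide 2 held no ir-MYB8 array of this group, and with slide as a block 1411 probes were called. A fit of the 6 arrays alone called 440.

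At 5 h after OS, 239 probes were higher and 389 lower in ir-MYB8. NIATv7_g06682.t1.cds1 was at 3.70 ± 0.41 in WT and -3.16 ± 0.57 in ir-MYB8 (SD, n = 3), 116-fold lower (limma adjusted p = 1.05e-06). NIATv7_g02841.t1.cds1, at -4.19 ± 0.32 in ir-MYB8 (SD, n = 3) with 2 of 3 arrays above background, was at least 99.4-fold lower than in WT (limma adjusted p = 2.75e-07), and both probes of its locus were called. Higher in ir-MYB8 were XLOC_014307.t1.cds1, at least 19.5-fold (n = 3; limma adjusted p = 3.00e-06), and NIATv1_g54551.t1.cds1, with a log2 fold change of 3.94 and an SE of 0.33 (n = 3; limma adjusted p = 4.47e-07), at least 15.1-fold, as 2 of 3 WT arrays were above background. Of the probes lower at 1 h after OS, 226 were also lower at 5 h, against 8.78 for independent lists, while 43 were higher at both times, against 3.17. All called probes kept their direction on slides 1 and 2, slide 3 held no WT array of this group, and the slide block gave 765 calls. The count depended on single arrays: it was 308, 382 and 398 without WT OS 5 h replicates 1, 2 and 3, and 311 and 394 without ir-MYB8 OS 5 h replicates 2 and 3. The authors' deposited values gave 484 higher and 514 lower probes, 48.5% higher in place of 38.1%.

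The difference between the lines' responses was tested as an interaction. At 1 h 131 probes responded higher and 322 lower in ir-MYB8 than in WT. Among the lowest responses was that of NIATv7_g26224.t1.cds1, which reached -0.27 ± 0.62 (SD, n = 3) after OS in WT and was not well above background after OS in ir-MYB8, nor in untreated leaves except on the array of ir-MYB8 control 1 h replicate 1 (limma adjusted p of the interaction = 0.00164). That array stood apart in detection, and the interaction of -6.18 was -4.95 without it, -6.80 without replicate 2 and -6.79 without replicate 3 of that group. PRID1968077029 was measured at -1.33 ± 0.32 (SD, n = 3) after OS in WT and in no other 1 h group (limma adjusted p of the interaction = 1.28e-05). NIATv7_g23932.t1.cds1 was measured after OS in ir-MYB8 and in no other 1 h group (limma adjusted p of the interaction = 0.00441), and its interaction of 4.27 was 4.87 without ir-MYB8 control 1 h replicate 1. NIATv7_g01522.t1.cds1 was measured in untreated WT leaves and in no other 1 h group (limma adjusted p of the interaction = 0.0264), but its adjusted p was 0.331 with normexp-corrected signals (0.00400 to 0.331 over the alternatives) and 0.0642 without the filter on dim probes. It was also no longer called, with adjusted p from 0.0530 to 0.0721, without ir-MYB8 control replicate 2 or 3, ir-MYB8 OS replicate 1 or 3, WT control replicate 2 or WT OS replicate 2 or 3. Of the 322 probes, 205 were also called higher after OS in WT at 5 h, on arrays whose means the interaction did not use, against 62.2 for independent lists. That baseline leaves out that the WT responses at both times overlap. Of the 7584 probes that rose in WT at 1 h, 3414 were also higher at 5 h. On slide 1, the only slide with all 4 groups, every called probe kept its direction, and with slide as a block 386 probes were called. Normexp-corrected signals gave 64 higher and 284 lower responses, array weights 599 and 775, and the 12 arrays alone 276 calls.

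At 5 h 8 probes responded higher and 83 lower in ir-MYB8, and 59 of the 83 had also responded lower at 1 h, against 0.797 for independent lists. NIATv7_g26224.t1.cds1 and PRID1968077029 again responded lower, measured after OS in WT at -1.13 ± 0.07 and -2.59 ± 0.69 (SD, n = 3) and in no other 5 h group (limma adjusted p of the interaction = 0.0180 and 6.29e-05). The first of these was no longer called, with adjusted p from 0.0526 to 0.0659, without ir-MYB8 control replicate 1, ir-MYB8 OS replicate 3, WT control replicate 2 or WT OS replicate 1. NIATv7_g10252.t1.cds1 was at 3.41 ± 1.08 in untreated and 1.89 ± 0.22 in OS-treated WT leaves, and at 2.30 ± 0.62 and 3.67 ± 0.36 in ir-MYB8 (SD, n = 3), an interaction of 2.89 with an SE of 0.56 (limma adjusted p = 0.0238) and of 2.27 without WT control 5 h replicate 3. For NIATv7_g31204.t1.cds1 the interaction was 1.46 with an SE of 0.30 (n = 3; limma adjusted p = 0.0379). With slide as a block 78 probes were called and the last 2 probes were not, with adjusted p of 0.0957 and 0.0882. Both also lost their call without the filter on dim probes (0.0615 and 0.109), and NIATv7_g31204.t1.cds1 with replicate number as a block (0.0512). Over the alternatives their adjusted p lay between 0.00393 and 0.0957 and between 0.00370 and 0.109. With 1 array left out, NIATv7_g10252.t1.cds1 lost its call without ir-MYB8 control replicate 2, ir-MYB8 OS replicate 2 or 3 or any WT OS array (0.0503 to 0.0971), and NIATv7_g31204.t1.cds1 without ir-MYB8 control or OS replicate 2 or 3, WT control replicate 3 or WT OS replicate 1 or 3 (0.0761 to 0.122). All calls kept their direction on slide 1, the only slide with all 4 groups. With the authors' deposited values 145 probes were called, 26.2% of them higher in place of 8.79%, and with normexp-corrected signals 166.

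Averaged over treatments and times, with 12 arrays per line, 1375 probes were higher and 1244 lower in ir-MYB8, and the median size of the called log2 differences was 0.39. NIATv7_g43706.t1.cds1 and NIATv7_g39881.t1.cds1 were among the lowest, with log2 fold changes of -5.48 (SE 0.24; limma adjusted p = 1.16e-11) and -5.34 (SE 0.22; limma adjusted p = 6.21e-12). Each was above background on 9 of the 12 ir-MYB8 arrays, at least 37.3-fold and 36.7-fold lower. XLOC_014307.t1.cds1 was measured on all 12 ir-MYB8 arrays and above background on no WT array, at least 17.4-fold higher (limma adjusted p = 1.10e-10). NIATv7_g24417.t1.cds3 was measured on 10 of the 12 ir-MYB8 arrays and no WT array and was at least 4.02-fold higher (limma adjusted p = 1.25e-06), and 1 of the 2 tested probes of its locus was called. In each of the 4 conditions separately, 23 probes were higher and 29 lower in ir-MYB8. Without PRID probes (3 and 5) these stood for 19 and 15 gene models or loci. Within slide 1, the only slide with all 8 groups, 99.8% of the calls kept their direction, and the slide block gave 3083 calls. With array weights 4293 probes were called and without the filter on dim probes 1438, 719 in each direction. The majority of higher probes turned with a minimum log2 change of 1, to 82 higher and 143 lower, and without ir-MYB8 OS 5 h replicate 2 (998 and 1038) or WT control 1 h replicate 3 (952 and 971).

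**Figure D3:**
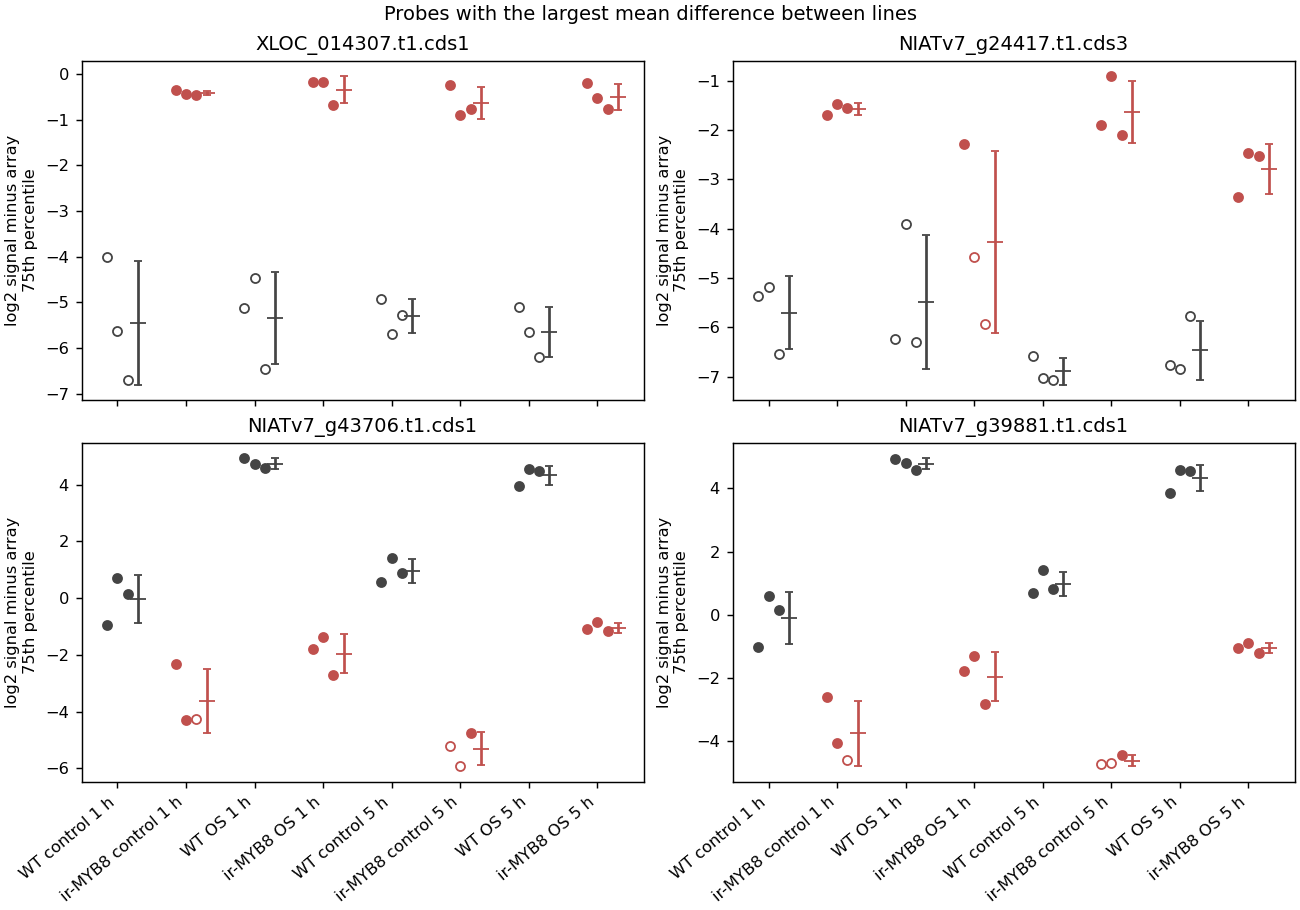
Level of the 4 probes named for the average difference between the lines, as log2 signal minus the 75th percentile of the array, for WT (grey) and ir-MYB8 (red). Circles are single arrays, open where not well above background, and bars are the mean ± SD of 3 arrays. XLOC_014307.t1.cds1 is open in all 12 WT arrays, and NIATv7_g43706.t1.cds1 reaches 4.75 in WT and -1.96 in ir-MYB8 at 1 h after OS.

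Harvest time alone, which also changes the time of day, was compared in untreated leaves of both lines. From 1 h to 5 h 5614 probes rose and 6602 fell, and of these 1630 rose and 1442 fell by at least 1 on the log2 scale. NIATv7_g13564.t1.cds2 and NIATv7_g00522.t1.cds1 were not well above background at 1 h and were at least 65.0-fold and 44.9-fold higher at 5 h (limma adjusted p = 5.16e-10 and 1.54e-10). NIATv7_g34280.t1.cds1 was at least 8.47-fold lower at 5 h (limma adjusted p = 3.20e-11). NIATv7_g11194.t2.cds2 had a log2 fold change of -5.22 with an SE of 0.41 (limma adjusted p = 9.96e-09), with 1 of the 6 later arrays above background (at least 13.9-fold), and all 4 tested probes of its locus were called lower. Slide 1, the only slide with all 4 groups, kept the direction of 99.4% of the calls, and the slide block gave 12556 calls.

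**Figure D4:**
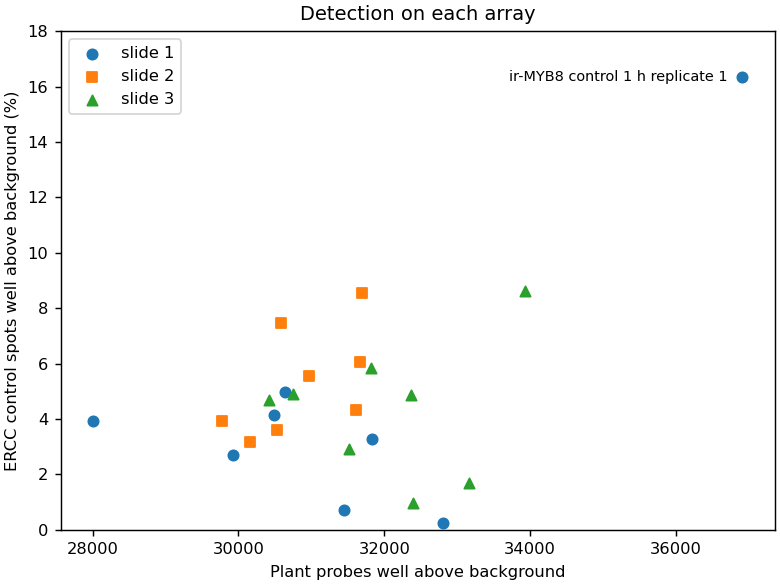
Share of the ERCC control spots without an outlier flag that were well above background (y axis, percent) against the number of plant probes well above background (x axis) on each of the 24 arrays, by slide. The array of ir-MYB8 control 1 h replicate 1 lies apart at 36909 probes and 16.3%, while the other 23 arrays lie between 28011 and 33926 probes and at most at 8.63%.

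The array of ir-MYB8 control 1 h replicate 1 stood apart from the others in detection. It enters the untreated 1 h comparison of the lines, the OS effect in ir-MYB8 at 1 h, the interaction at 1 h, the average over conditions and the comparison of harvest times. Without it these called 132, 18974, 359, 2840 and 11525 probes.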

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

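Tests chosen only after the results were seen are those of the array that stood apart, of the interaction at 1 h, of shared targets among probes higher in ir-MYB8, and the counts of correlated partners. The others were chosen before their result was seen.

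The response to OS differed between the lines in a direct test of the difference for 453 probes at 1 h and 91 at 5 h. The named probes with such a difference had interactions on the log2 scale of 4.27 (NIATv7_g23932.t1.cds1; 4.87 without ir-MYB8 control 1 h replicate 1), 3.80 (NIATv7_g01522.t1.cds1), -6.18 (NIATv7_g26224.t1.cds1; -4.95, -6.80 and -6.79 without ir-MYB8 control 1 h replicates 1, 2 and 3) and -5.29 (PRID1968077029) at 1 h. At 5 h they were 2.89 (NIATv7_g10252.t1.cds1; 2.27 without WT control 5 h replicate 3), 1.46 (NIATv7_g31204.t1.cds1), -5.30 (NIATv7_g26224.t1.cds1) and -5.11 (PRID1968077029). These fitted values are no measured folds where groups were not well above background, which holds for all but NIATv7_g10252.t1.cds1 and NIATv7_g31204.t1.cds1. Relabelling the lines within each treatment gave at least as many calls as the real labels in 5 of 100 splits at 1 h, where the real count was 453 and the highest other 933, and in 11 of 100 at 5 h, where the real count was 91 and the highest other 1805. Chance is therefore not excluded by these splits. Of the other splits as large as the real one, 4 of 4 at 1 h and 7 of 10 at 5 h swapped most line labels in 1 treatment and not in the other, which turns the difference between the lines itself into an interaction. Of the 100 splits, 49 at 1 h and 54 at 5 h were of this kind, so at 5 h the share among the large splits was near that of all. The other splits, apart from the real one, reached at most 402 and 135 calls. On arrays of the other time, which these splits do not weigh, 59 of the 83 probes with a lower response at 5 h also had one at 1 h, against 0.797 for independent lists.

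Lower responses in ir-MYB8 at 1 h were the first pattern weighed. Without the array of ir-MYB8 control 1 h replicate 1, 72.4% of the 322 probes were still called lower. With slide as a block it was 74.5%, and after quantile normalization 78.6%. Most of these calls therefore did not depend on that array, on leaving slides out of the fit or on the scaling used. The probes were called on these same arrays, so part of each share is built in. Of the 453 calls in both directions 318 were kept without that array. Without 1 of the other arrays compared 293 to 382 were kept, so its loss did not stand out. The lost calls may still owe something to that array, the slides or the scaling. The silencing of MYB8 stays an open explanation, as does a difference between the lines that has nothing to do with MYB8, since 1 transgenic genotype was compared.

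The array of ir-MYB8 control 1 h replicate 1 was the second: of its control spots, which no comparison used, 16.3% of the ERCC, 21.7% of the ETG and 91.0% of the E1A spots were well above background, against at most 8.63%, 8.76% and 75.2% on the other arrays. The excess is not confined to ERCC spots. Of the 308 negative control and 35 dark corner spots, 0% were well above background on every array, so that share could not show an excess. Their median processed signals on this array were 5.01 and 5.50, against at most 4.95 and 5.54 on the other arrays. The brightest E1A spot of this array, at 21087, was dimmer than that of any other array (31910 or more). Which RNA was added for the 3 kinds with an excess is not given in the sources used here. Unspecific signal therefore stays open as an explanation for the 36909 detected probes of this array. Its median signal of 50.7 was the highest (at most 37.8 on the others), as was its mean negative control signal of 47.7 (at most 43.1), while its 75th percentile of 376 was not; a brighter scan or more labelled RNA alone multiplies all signals, and is argued against by the ratio of 75th percentile to median, 7.41 against 10 to 15.6 on the other arrays. A property of the group is argued against as well, since the other arrays of the group detected at most 30972 probes and lay within the range of the other 21 arrays, whose highest was 33926. A difference in the pooled plants was not tested.

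Probes that differed between the lines in all 4 conditions were the third. Among the 23 higher in ir-MYB8, 22 (95.7%) were still called higher in all 4 with slide as a block, which argues against the slides. Their deviations from the group means had a median correlation of 0.229 (across the 24 arrays), above the 99th percentile of random sets of 0.0750 and far below what a single shared target would need, and 15 of the 23 had a partner with a correlation over 0.8. Whether subsets of them read one transcript cannot be told apart from joint regulation without probe sequences. The 29 lower probes, from 15 loci and 5 PRID probes, had a median correlation of 0.0402, under the 95th percentile of random sets of 0.0496, so they did not as a set read one target, although 13 of them had a partner over 0.8.

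For the comparisons of 3 against 3 arrays, the 10 splits are too few for a share under 0.05, and in each the real split was the 1 of 10 with as many calls. The real counts and the highest of the other splits, over the 33507 probes without missing values, were 20442 and 1 for OS in WT at 1 h, 15006 and 0 at 5 h, 19649 and 10 for OS in ir-MYB8 at 1 h, and 13918 and 2 at 5 h. Between the lines they were 146 and 2 in untreated leaves at 1 h, 235 and 1 at 5 h, 1201 and 84 at 1 h after OS, and 628 and 1 at 5 h. Every other split of 3 against 3 arrays mixed both real groups, so a real difference enters the spread and lowers its calls. The counts of the other splits are therefore no estimate of the calls without a difference. For the average difference between the lines 1 of 100 splits, the real one, gave 2621 calls and the highest other 75. For harvest time 1 of 100 gave 12207, and the highest other, which swapped 10 of the 12 labels and so lay close to the mirror of the real split, gave 6816. For the last 2, a share of 1 in 100, the smallest that 100 splits can give, makes chance unlikely and does not exclude it.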

How the results depend on the processing

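The array of ir-MYB8 control 1 h replicate 1 was left out of comparisons that do not use it only after the data were seen; all other alternatives were chosen before. Counts are of probes called in both directions, and the cause of a change was not tested unless stated. Counts moved by over 1.5 times as follows. Normexp on the median signals gave 166 for the interaction at 5 h (91 in the fit reported). The authors' deposited values gave 998 for the lines at 5 h after OS (628) and 145 for the interaction at 5 h. Without the filter on dim probes, which tests more probes, counts were 80 for untreated leaves at 1 h (146) and, rounded, 1.1e+02 at 5 h (58 higher and 49 lower; 235), 332 for the lines at 5 h after OS, 261 for the interaction at 1 h (453) and 1438 for the average (2619). The stricter filter gave 383 for untreated leaves at 5 h. Fitting only the arrays compared, with fewer samples for the spread, gave 25 and 28 for untreated leaves, 440 (1201) and 304 for the lines after OS at 1 h and 5 h, and 276 and 44 for the interactions. An intensity trend gave 417 for untreated leaves at 5 h and 156 for the interaction at 5 h. Array weights gave 771 for untreated leaves at 1 h, 3648 and 1455 after OS, 1374 and 151 for the interactions and 4293 for the average. The weights ran from 0.28 for ir-MYB8 control 5 h replicate 1 to 4.1 for WT OS 1 h replicate 1. A minimum log2 change of 1, by construction, left 11625 and 6693 for OS in WT, 10712 and 5743 in ir-MYB8, 147 for untreated leaves at 5 h, 604 and 335 after OS, 225 for the average and 3072 for harvest time. Quantile normalization and the blocks moved no count that far.

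With 1 array left out, counts ranged from 18897 to 20667 and 12294 to 15297 for OS in WT at 1 h and 5 h, from 17978 to 19018 and 11633 to 14149 in ir-MYB8, from 85 to 132 and 83 to 296 for untreated leaves, from 894 to 1248 and 308 to 664 after OS, from 313 to 508 and 61 to 132 for the interactions, from 1923 to 2840 for the average and from 10939 to 12332 for harvest time. Counts that moved by over 1.5 times were those of untreated leaves, at 1 h without ir-MYB8 replicate 3 (89) or WT replicate 3 (85) and at 5 h without ir-MYB8 replicate 1 (114) or WT replicate 3 (83), and those at 5 h after OS without WT replicate 1, 2 or 3 (308, 382 and 398) or ir-MYB8 replicate 2 or 3 (311 and 394). Where an array is left out, the spread of the remaining 2 is pooled with that of the other groups.

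No named probe reversed, but sizes depended on the processing. Of 48 fitted values of named probes, 46 were smaller by over 1.5 times with normexp and 45 with the authors' deposited values, while quantile normalization moved 2 and the slide block 1 that far. Of 290 values of named probes under other processing 282 kept their call and 8 lost it, and of 432 with 1 array left out 403 kept it and 29 lost it. Replicate numbers were not taken to pair the samples, since 35 of 84 same-numbered pairs, not all, had deviations correlated above 0.1. Their mean r was 0.0606, against -0.0298 for other numbers, and 13 of 24 arrays correlated best with their own number. Arrays of the same slide had a mean r of 0.0918, against -0.0422 for other slides. Slide 1 held all arrays of replicate 1 and no others, so a shared number and a shared slide cannot be told apart there. These values do not show that the samples were unpaired. With a replicate block the counts were 20628, 15276, 19919 and 14231 for OS, 169, 277 and 1286 between the lines in the untreated and the 1 h OS comparisons, 482 and 111 for the interactions, 2698 for the average and 12402 for harvest time. The gene list tests and their alternatives were not run, since no gene names were matched. A probe that no array of a group measured well above background carries only a bound there, and 24869 of the 33528 tested probes were well above background on all arrays.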

Other observations

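Tests chosen only after the results were seen are those of the overall size of the response, of OS-induced probes among those lower in ir-MYB8, and of XLOC loci other than in WT at 1 h. The others were chosen before their result was seen.

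A hypothesis was that probes lower in ir-MYB8 after OS are drawn from those that OS induces. Of the 389 probes lower at 5 h, 257 (66.1%) rose in WT at 1 h, on arrays whose means the comparison of the lines did not use. In 1000 random sets of tested probes matched on mean signal the share was at most 29.3%. These sets were not matched on spread or on the WT response at 5 h. Of the 757 probes lower at 1 h after OS, 394 were higher after OS in WT at 5 h, against 146 for independent lists, a baseline that leaves out the overlap of the WT responses at both times. Of the probes higher in ir-MYB8 at 5 h after OS, 49 of 239 rose in WT at 1 h, against 54.1.

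A hypothesis was that OS moves all responding transcripts less in ir-MYB8. Over the 11152 probes with a mean response over both lines above 1 in size on the log2 scale, the mean response of ir-MYB8 was 0.915 times that of WT at 1 h (2-sided exact permutation of line labels within treatment, p = 0.06, 400 relabellings). At 5 h it was 0.906 times over 6189 probes (2-sided exact permutation p = 0.225). Neither passed 0.05, and a p that misses the threshold does not show equal responses. Without the array of ir-MYB8 control 1 h replicate 1 the 1 h ratio was 0.938 (2-sided exact permutation p = 0.105, 200 relabellings).

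Consecutive NIATv7 model numbers responded alike more often than shuffled ones. Across 9730 pairs, which are not independent replicates, the log2 fold changes in WT at 1 h after OS correlated with r = 0.132, against at most 0.0318 in 1000 shuffles. Without pairs whose within-group deviations correlated above 0.5, r was 0.0777 over 8976 pairs, against at most 0.0305, so probes that read one transcript may account for part of the value. Whether they account for all of it cannot be told, since pairs that share a target can stay under 0.5. For the average difference between the lines r was 0.0359. Whether the numbers follow the order on the genome is not given in the sources used here.

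Loci with XLOC identifiers were called less often than NIATv7 models of the same mean signal at 1 h after OS. At 5 h this was not seen, and the difference between the times was not tested. Of the 919 tested XLOC probes 50.4% were called in WT and 48.7% in ir-MYB8 at 1 h, below the central 95% of random sets of NIATv7 probes of the same mean signal, 55.7% to 61.8% and 53.4% to 59.7%. At 5 h the shares of 42.1% in WT and 35.7% in ir-MYB8 lay within those of the random sets, 37.4% to 43.6% and 34.0% to 39.8%.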
